A study of Caenorhabditis elegans with 26 samples.

How the data were processed

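Whole worms of the wild-type C. elegans strain N2 were sampled through larval life in 2 time courses, and total RNA was sequenced after removal of ribosomal RNA. In course A, larvae grew on NGM plates with the bacterium OP50 and were sampled every 1 h, which gave 16 libraries titled 21 to 36 h. In course B, larvae grew on peptone-rich NGM plates with the bacterium NA22 and were sampled every 2 h, which gave 10 libraries titled 18 to 36 h. Per the labels, the course A worms were harvested 1 h later than the title says, because this course grew slowly and the title lies nearer to the developmental time. Times in the text are those of the titles unless harvest times are named. RNA was isolated with Tri-Reagent and libraries were made with the ScriptSeq v2 kit.

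The deposited count table holds raw counts per gene, 1 column per library, for 20182 genes under WormBase identifiers. The deposited normalized table holds log2 values. Recomputed as the log2 of the count, scaled to the mean total of its own course, plus 8, they differed from the authors' values by at most 5e-05. Because the authors scaled course A to a mean total of 20.996 and course B to 29.099 (in 1e6 counts), the log2 values of the courses lie 0.47 apart at the same share of counts. The aligner, the counting tool, its treatment of strands and of reads with several matches, the genome build and the annotation are not given in the sources used here. Reads shared between near-identical genes, and reads from the opposite strand or from overlapping genes, can therefore enter a gene's count. Gene names were joined by identifier for 18778 of the genes. No coordinates are given, since the build behind the counts is not stated.

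Total counts per library ran from 16241561 to 29911888 in course A and from 22587893 to 36083371 in course B. A gene with 0 counts in a library can still hold up to 3 counts' worth of RNA, which is 0.0932 to 0.186 CPM (counts scaled to a library total of 1e6) depending on the library. These floors cover counting error only, as the libraries carry no molecular identifiers. CPM values use TMM-scaled totals.

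Counts were fitted with edgeR 4.0.16 (quasi-likelihood F tests with robust dispersion) and TMM factors in R 4.3.3. No time point was sampled more than once, so the spread came from the deviations of the libraries from a curve with an intercept, linear time, and a cosine and sine of 8 h. Neighbouring times can deviate together, which such a fit does not allow for. Genes entered a fit with at least 10 counts at the median library size in at least 3 libraries. Each course was fitted apart. A gene was called oscillating at a Benjamini-Hochberg adjusted p under 0.05 (cosine and sine tested together) and a fitted peak-to-trough difference of at least 1 on the log2 scale. It was called a trend gene at an adjusted p under 0.05 for linear time and a change of at least 1 on the log2 scale over 15 h. Peak times are given within the cycle from 24 to 32 h. The courses were compared at the 8 shared times from 22 to 36 h with time as a block (16 libraries), and by interaction terms over all 26 libraries. The standard errors come from the same fits.

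The comparisons, tests, thresholds, 25 gene lists and the rule for naming genes were fixed before the data were examined. List members among the oscillating genes were tested with Fisher's exact test, two-sided, and the clustering of their peak times with 10000 random lists of the same size. The trend of a list and its difference between the courses were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, and again with an estimated correlation. Each family of list tests was adjusted over the lists. No member of the mitochondrial genome list or of the ribosomal RNA list is in the deposited table. Of the 21 heterochronic names, 15 were in the table, and the microRNAs were not among them. The core histone list was taken by gene name (his) and also holds other histones, such as the linker histone gene his-24.

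The rule named all 16 molting and oscillator regulators. From every other list it took the 2 members with the largest peak-to-trough difference, the 2 with the largest trend and the 1 with the largest course difference, among those called. From the whole table it took the 5 largest oscillations, the 5 largest rises, the 5 largest falls and the 5 highest and 5 lowest course differences, among called genes with a gene name and a mean of at least 10 CPM. Other genes named in the text were chosen after their values were seen, and the text says where.

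Alternatives were DESeq2's size factors, total counts as the only scaling, DESeq2 1.42.0 and limma on the deposited log2 values as other tests, no low count filter, periods of 7 and 9 h, quadratic time, other fold minimums, the 8 shared times alone, harvest times, and each library left out in turn. Added after the data were seen were the scaling by total counts, a rescaling of course B that sets the median difference at the shared times to 0, the comparison of course B with course A 3 h earlier (7 pairs of libraries), the fits with course B moved back by the median offset, the count of peaks around that offset, and the tests of gene families. The fits were tested on simulated data with the totals of the real libraries and a dispersion of 0.03. The simulated genes had no other cycle, trend or lag. Genes with a simulated change of 1 on the log2 scale were scored at an adjusted p under 0.05 with no minimum difference. Recovery was 79.1% for oscillation in course A, 64.2% in course B and 100% for the matched difference. It was 28.4% for a difference in oscillation between the courses and 37.3% for a difference in trend. The calls in the text, apart from a difference in oscillation, also ask for at least 1, which fewer such genes would pass. All deposited libraries were used.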

Results

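Total RNA was measured in whole N2 larvae in 2 separate time courses over larval development, and both were examined for cycles, for lasting changes with time and for differences between them. Course A has 16 libraries, taken every 1 h from 21 to 36 h by title on plates with OP50, and course B has 10, taken every 2 h from 18 to 36 h on peptone-rich plates with NA22. Library totals ran from 16241561 to 29911888 counts in course A and from 22587893 to 36083371 counts in course B. The 50 most abundant genes of a library held a median of 14.4% of its counts in course A and 15.6% in course B, and the median TMM factors were 1.07 and 0.892. No time point was sampled more than once. The p-values therefore measure only the spread of single libraries around a fitted curve, not the spread between cultures, and bacterium, medium and day of growth all change with the course.

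The first question was which transcripts cycle with an 8 h period, and among them were many genes that build and shed the cuticle. The peak-to-trough difference of mlt-10, a gene needed for molting, was 6.22 ± 0.21 (log2, standard error of the fit) over the 16 libraries of course A and 6.06 ± 0.76 over the 10 of course B. The cuticle collagen col-146 spanned 8.25 ± 0.73 and 7.29 ± 1.04, and fbn-1, which encodes a fibrillin-like matrix protein, spanned 5.59 ± 0.83 and 6.10 ± 0.56. Among the 130 cuticle collagens tested in both courses, 96 oscillated in both (110 adjusted over the list alone), an enrichment at an adjusted p of 1.92e-46 by Fisher's exact test. Of the 33 molting enzymes and matrix genes, 25 oscillated in both (25 adjusted over the list alone), at an adjusted p of 4.79e-13. Members of the collagen family resemble each other, so that single collagens can share reads.

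Regulators from the molting and oscillator list cycled as well, with 9 of the 16 called in both courses (11 adjusted over the list alone, adjusted p = 0.000951, Fisher's exact test). bed-3, a zinc finger gene needed for molting, spanned 5.09 ± 0.33 in course A and 4.80 ± 0.82 in course B. The grainyhead gene grh-1 spanned 3.31 ± 0.25 and 3.58 ± 0.41, and lin-42, the worm relative of the clock gene Period, 3.52 ± 0.27 and 2.87 ± 0.42. peb-1, nhr-41, nhr-91 and ztf-6 were called too, with differences from 1.28 to 4.52. The nuclear receptor gene nhr-23 was called with 1.89 ± 0.38 and 2.55 ± 0.60. Its adjusted p in course B, 0.0349, rose to between 0.0590 and 0.0972 without the library of 20, 22, 24, 28, 30, 32 or 34 h. myrf-1 was called with 1.94 ± 0.53 and 2.02 ± 0.23, and its adjusted p in course A, 0.0291, rose to between 0.0518 and 0.108 without the library of 25, 26, 29, 30 or 34 h. The difference of blmp-1 was 1.14 in course A and 0.89 in course B, below the minimum, while nhr-25, nhr-85 and elt-3 passed in course A and had adjusted p values of 0.220, 0.0520 and 0.0513 in course B. nhr-67, myrf-2 and nhr-6 passed in neither.

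Signalling, pharyngeal and detoxification genes made up further oscillating groups. Of 41 hedgehog-related genes, many of them made by the skin, 35 oscillated in both courses (35 adjusted over the list alone; adjusted p = 5.74e-21), and grd-6 spanned 6.93 ± 0.76 and 7.76 ± 0.87. Of 26 patched-related genes, 19 did (19 adjusted over the list alone; adjusted p = 9.54e-10), with ptr-16 at 5.58 ± 0.34 and 6.25 ± 0.94. Of 37 pharyngeal cuticle and gland genes, 29 did (31 adjusted over the list alone; adjusted p = 1.25e-15). Their peaks lay close together, around 26.1 h in course A and 28.9 h in course B (vector strength 0.747; permutation test with random lists, adjusted p = 0.0012, the smallest these draws can give). Within this group, idpc-5 spanned 7.22 ± 0.83 and 8.38 ± 0.86, and the paralogs abu-10 and abu-11, whose near-identical members can share reads, spanned 6.59 and 6.52 in course A and 8.26 and 8.39 in course B. The other genes with the largest swings were pqn-54, at 6.67 ± 0.84 and 8.36 ± 1.09, and dct-5, at 7.32 ± 0.97 and 8.06 ± 1.25. Among 163 detoxification genes 61 oscillated (70 adjusted over the list alone; adjusted p = 3.90e-10), among them the glutathione transferase gene gst-41 at 5.07 ± 0.58 and 5.27 ± 0.74. From lists that did not pass as a whole, the gut protease gene cpr-6 spanned 2.92 ± 0.33 and 3.06 ± 0.32, and fasn-1, which encodes fatty acid synthase, 2.53 ± 0.29 and 2.72 ± 0.28.

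In other groups no gene was called in both courses. The count of genes oscillating in both courses was 0 of 74 ribosomal protein genes (adjusted p = 7.49e-06), 0 of 41 germline and oocyte genes (adjusted p = 0.00275), 0 of 30 cell cycle genes (adjusted p = 0.0244), and 0 of 23 core histones and 0 of 23 neuronal genes (adjusted p = 0.0456 each), all by Fisher's exact test on edgeR calls. The count in each of these lists was also 0 at an unadjusted p under 0.05, with DESeq2, with limma, and adjusted over the list alone. The remaining lists did not pass the test. Their counts were 2 of 15 heterochronic genes (1 adjusted over the list alone), 3 of 40 sperm genes (0), 6 of 17 intestinal genes (6), 3 of 17 genes of the vulva, uterus and somatic gonad (3), 25 of 120 C-type lectins (26), 1 of 8 lysozymes (1) and 4 of 13 fatty acid genes (4). They were 0 of 3 yolk protein genes, 0 of 19 body wall muscle genes, 0 of 15 propionate and vitamin B12 genes and 0 of 14 heat shock genes. These 4 lists held 0, 0, 0 and 1 genes at an unadjusted p under 0.05, 0, 0, 0 and 1 with DESeq2, and 0 each with limma.

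**Figure D1:**
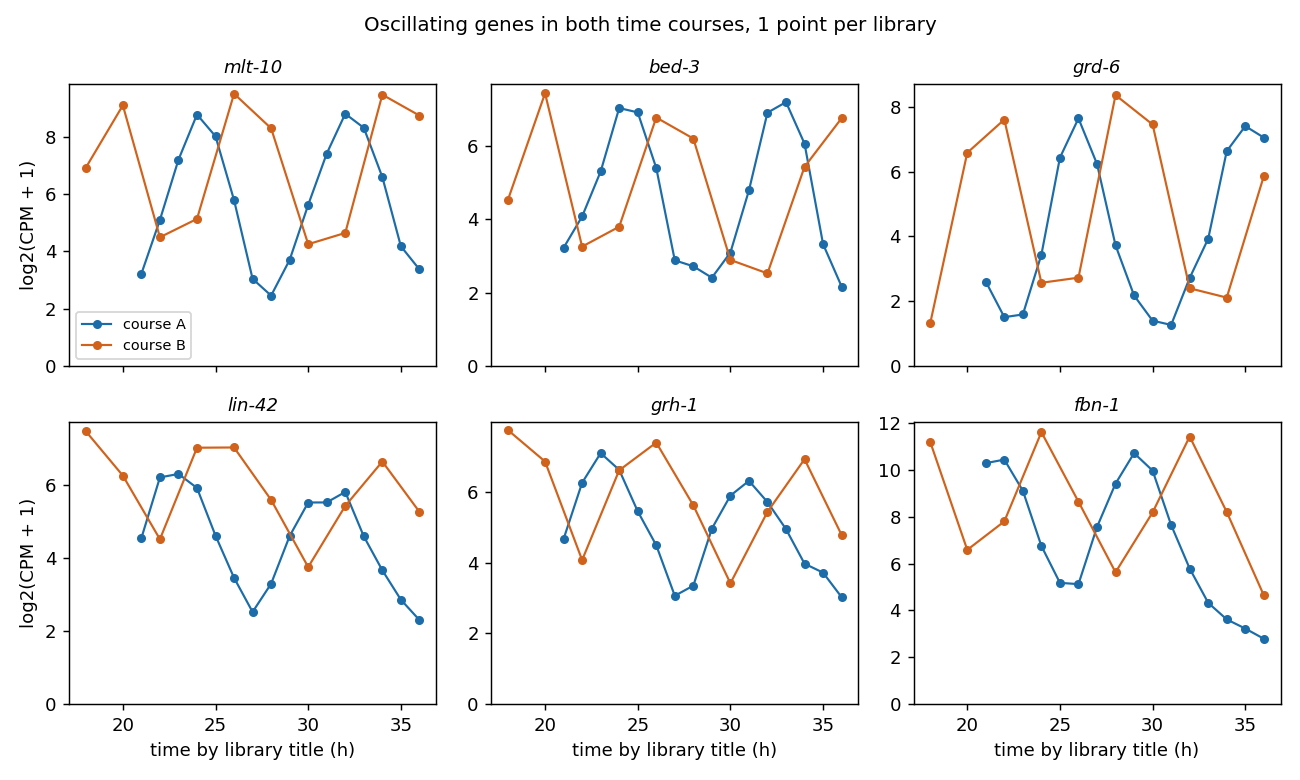
Expression of 6 oscillating genes, as log2 of CPM plus 1 on the y axis against the time by title in h on the x axis, with 1 point per library (16 in course A, blue; 10 in course B, orange). Each gene falls and rises again within a course, and the curve of course B runs behind that of course A; mlt-10 had its fitted peaks at 24.1 and 26.9 h.

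Over all genes, 3619 of 15888 tested (22.8%) oscillated in course A and 3147 of 15003 (20.98%) in course B. These counts can include genes that rose along a curve without a cycle, since the fit allows only linear time besides the cosine and sine. In course A, 12 sperm genes and 5 yolk genes were among them. Of the 14920 genes tested in both, 2457 were called in both, where independent lists would share 716. The median peak-to-trough difference was 2.31 over all genes called in course A and 2.40 over all called in course B, and the differences of the 2457 genes correlated between the courses (Spearman's rho 0.934 across genes, which are not independent replicates). The period with the most calls was 8.75 h in course A and 7.75 h in course B. With a 7 h period the calls fell to 2054 in course A and 36 in course B. Course A gave 3923 with 9 h and 3456 with 10 h, so this course did not single out 8 h. With 9 h course B gave 0 with edgeR, against 2514 at an unadjusted p under 0.05, 1696 with DESeq2 and 0 with limma.

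The next question was whether the courses keep the same clock, and the same genes peaked later in course B by title. The peak of grh-1 lay at 31.3 h in course A and 25.9 h in course B, 1 cycle on, and that of grd-6 at 26.5 and 29.1 h. cpr-6 peaked at 24.2 and 26.8 h and ptr-16 at 24.7 and 27.4 h. The collagens had their mean peak at 25.8 h in course A and 28.3 h in course B, the hedgehog-related genes at 24.7 and 27.5 h, and the molting enzymes and matrix genes at 31.5 h and, in the next cycle, 26.2 h. The median offset over the 2457 genes was 2.73 h, with 5% of genes below 2.12 h and 5% above 3.18 h. A rule set beforehand asked for peaks no more than 2 h apart, and 88 genes (3.58%) met it. Around the median offset, a setting chosen after the data were seen, 2445 genes (99.5%) lay within 2 h and 2381 within 1 h. Without single libraries the count of 88 moved to 48 (course A, 32 h), 56 (course B, 30 h), 38 (course B, 32 h) and 48 (course B, 36 h). With harvest times in place of title times the offset was 1.73 h. Course A was thus ahead of course B on both scales, and further ahead by title, although the labels describe course A as slow. Title times therefore do not put the courses on the same developmental clock.

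**Figure D2:**
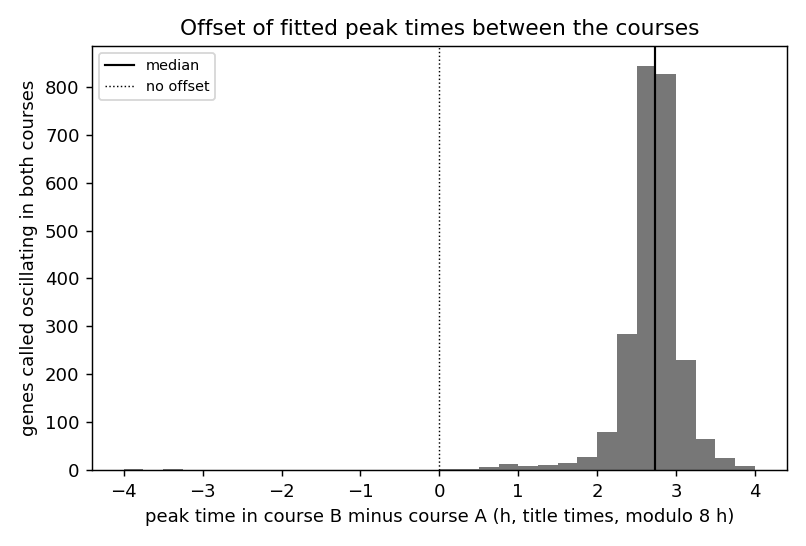
Offset of the fitted peak time, course B minus course A in h on the x axis (title times, modulo 8 h), for the 2457 genes called oscillating in both courses, with the number of genes per bin on the y axis. The bars stand around the median of 2.73 h (solid line), away from an offset of 0 (dotted line).

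Apart from the cycle, genes could rise or fall through a course, and sperm, oocyte and yolk genes rose. spe-11, a sperm gene needed by the embryo, went from a mean of 0.927 CPM at 21 to 28 h to 91.01 CPM at 29 to 36 h in course A. In course B it had 0 counts in the 4 libraries from 18 to 24 h, which allows up to 0.131 CPM in a library, and a mean of 108 CPM at 30 to 36 h. puf-5, an RNA-binding gene of the oocyte, rose by 4.88 ± 0.60 over 15 h in course A and by 4.90 ± 0.70 in course B (log2), and the meiotic gene lab-1 by 6.27 ± 0.47 and 5.45 ± 0.68. The yolk gene vit-2 went from 0.357 to 241 CPM in course A and from 0.0320 CPM, on 4 counts, to 44.0 CPM in course B. In both courses 39 of 40 sperm genes rose (39 adjusted over the list alone), 36 of 41 germline and oocyte genes (36) and 3 of 3 yolk genes (3). The msp and nspd families among the sperm genes have near-identical members that can share reads. With camera the adjusted p was 1.24e-32 (course A) and 3.14e-17 (course B) for sperm, and 0.0530 and 0.426 with an estimated correlation. For germline it was 4.73e-13 and 9.57e-22, with 0.0530 and 0.0348 with an estimated correlation, and for yolk 8.51e-09 and 0.0691, with 0.0530 and 0.562 with an estimated correlation.

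Many neuronal genes and some regulators of early stages fell as a share of whole-worm RNA, which need not be a fall in each cell. cho-1, the choline transporter of cholinergic neurons, fell, with changes over 15 h of -1.65 ± 0.19 in course A and -1.38 ± 0.14 in course B, as did unc-47, the vesicular GABA transporter, with -1.37 ± 0.22 and -1.67 ± 0.19. hbl-1, a hunchback-like regulator of early larval fates, changed by -2.23 ± 0.34 and -2.90 ± 0.25. The tubulin gene tba-8 went from 36.9 to 1.22 CPM in course A and from 74.9 to 1.88 CPM in course B, and daf-9, a cytochrome P450 of steroid hormone synthesis, changed by -3.94 ± 0.40 and -2.69 ± 0.58. In both courses 14 of 23 neuronal genes fell (14 adjusted over the list alone; camera adjusted p = 4.08e-08 and 4.93e-13, with adjusted p = 0.0347 and 0.0633 with an estimated correlation). The same held for 5 of 15 heterochronic genes (5; 0.000207 and 0.00448, with adjusted p = 0.0347 and 0.276 with an estimated correlation). It also held for 7 of 16 molting and oscillator regulators (7; 0.000375 and 0.00107, with adjusted p = 0.0860 and 0.0633 with an estimated correlation). Of 17 genes of the vulva, uterus and somatic gonad 3 fell (3; 0.0192 and 0.0270, with adjusted p = 0.0530 and 0.144 with an estimated correlation), among them nhr-67, which changed by -2.18 ± 0.30 and -2.03 ± 0.21.

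Cuticle genes went both ways. Of 130 collagens tested in both courses, 42 rose and 6 fell in both (41 and 5 adjusted over the list alone), and the list passed in course B (adjusted p = 0.00107; adjusted p = 0.117 with an estimated correlation) and not in course A (0.227). col-175 went from 0.433 to 1354 CPM in course A and from 0.0554 CPM, on 6 counts, to 1868 CPM in course B, and col-122 from 0.0561 CPM, on 10 counts, to 286 CPM and from 0.0316 CPM, on 3 counts, to 126 CPM. The hedgehog-related genes wrt-6 and grl-27 rose by 4.70 ± 0.39 and 7.38 ± 1.26 in course A and by 2.97 ± 0.57 and 4.13 ± 0.40 in course B and were 2 of the 3 among 41 hedgehog-related genes that rose (3). Of the 33 molting enzymes and matrix genes 6 fell and 1 rose (5 and 1), the chitin synthase gene chs-1, by 2.50 ± 0.21 and 2.69 ± 0.34. Whole worms were sampled, so the rise of chs-1 cannot be placed in the cuticle and need not belong to it. Of 26 patched-related genes 4 fell (3), with ptr-22 at -2.42 ± 0.73 and -2.52 ± 0.52. Of 37 pharyngeal genes 4 fell (4), among them the homeobox gene ceh-22, which changed by -1.90 ± 0.31 and -1.57 ± 0.19. That list's camera test in course A pointed down (adjusted p = 0.0357; adjusted p = 0.672 with an estimated correlation) while its median trend there was 0.11.

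Some members of other groups rose or fell as well. Of 120 C-type lectins 19 rose and 8 fell in both courses (20 and 9 adjusted over the list alone), and of 163 detoxification genes 10 rose and 21 fell (10 and 20). The transferase gene gst-14 changed by -4.97 ± 0.60 and -4.41 ± 0.58, and cyp-37B1 rose by 4.995 ± 0.82 and 1.65 ± 0.37. Of 30 cell cycle genes 5 rose and 1 fell (5 and 1; camera adjusted p = 0.0159 in course B, adjusted p = 0.764 with an estimated correlation), with the cyclin gene cyb-2.2 at 4.013 ± 0.27 and 3.95 ± 0.37. Of 23 genes of the core histone list 2 rose and 1 fell (2 and 1; adjusted p = 0.0148 for the list in course A, adjusted p = 0.538 with an estimated correlation). The gene that fell, his-24, encodes a linker histone, so no core histone is shown to fall by this call. Of 74 ribosomal protein genes 2 rose (2), among them rpl-11.1 by 1.71 ± 0.18 and 1.94 ± 0.11, while the list as a whole pointed down in course A (median -0.37, adjusted p = 0.000718; adjusted p = 0.672 with an estimated correlation). hsp-70, a heat-inducible chaperone, rose by 2.55 ± 0.38 and 3.17 ± 0.35 and was 1 of 3 heat shock genes of 14 that rose (3). Over all genes, 3354 rose and 2021 fell in course A, and 2403 rose and 1821 fell in course B. Of the genes tested in both, 2237 rose in both and 1170 fell in both, where independent lists would share 460 and 236, and 5 went opposite ways.

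**Figure D3:**
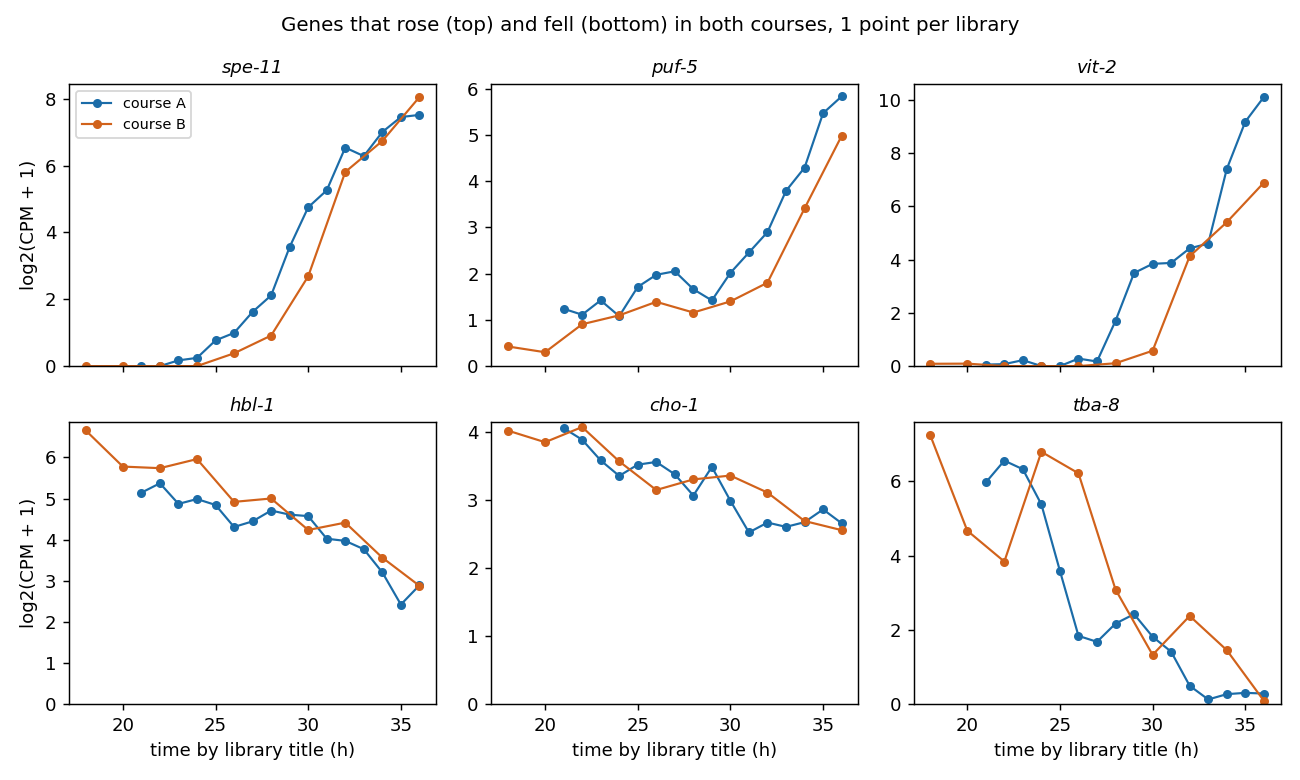
Expression of 3 genes that rose (top) and 3 that fell (bottom) in both courses, as log2 of CPM plus 1 on the y axis against the time by title in h on the x axis, with 1 point per library (course A blue, course B orange). spe-11 starts near 0 in both courses and ends with means of 91.01 CPM (29 to 36 h, course A) and 108 CPM (30 to 36 h, course B), and tba-8 ends at 1.22 and 1.88 CPM.

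The third question was what differed between the courses at the 8 shared title times, and several of the genes named for their difference act in metabolism. The lists of intestinal, fatty acid, propionate and vitamin B12, and detoxification genes did not pass the camera test there (adjusted p = 0.217, 0.0690, 0.630 and 0.624). Against course A 3 h earlier, a comparison chosen after the data were seen that uses 7 of the same course B libraries, the fatty acid list passed as lower in course B (adjusted p = 0.000164; adjusted p = 0.432 with an estimated correlation), with 3 of 13 genes lower. The detoxification list did too (adjusted p = 0.0467; adjusted p = 0.498 with an estimated correlation), with 12 of 170 higher and 26 lower. By total counts alone these were 5 fatty acid genes lower, and 6 detoxification genes higher and 42 lower. argk-1, an arginine kinase gene, had a mean of 8.83 CPM in course A and 243 CPM in course B, a difference of 5.08 ± 0.53 (log2, adjusted p = 0.000507) that was higher in 8 of 8 pairs. The transporter gene pgp-1 had 49.97 and 435 CPM (3.08 ± 0.22), the lectin gene clec-17 2.58 and 19.2 CPM (3.19 ± 0.32) and the glutathione transferase gene gst-38 11.3 and 63.6 CPM (2.49 ± 0.31), each higher in course B in 8 of 8 pairs. Lower in course B in 8 of 8 pairs were acdh-2, an acyl-CoA dehydrogenase gene, at 36.6 and 0.356 CPM (-5.79 ± 0.83), fat-7, a fatty acid desaturase gene, at 13.5 and 0.312 CPM (-5.60 ± 0.39), clec-47 at 71.8 and 3.41 CPM (-4.47 ± 0.36), the lysozyme gene lys-6 at 2.08 and 0.115 CPM (-4.25 ± 0.37) and ugt-15, a glucuronosyltransferase gene, at 3.70 and 0.120 CPM (-4.54 ± 0.54). All 9 were also past the threshold with course B set against course A 3 h earlier, where the shared libraries of course B make some agreement expected, with argk-1 at 4.78 ± 0.39, pgp-1 at 3.07 ± 0.20, acdh-2 at -5.69 ± 0.52 and fat-7 at -5.39 ± 0.20.

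Genes that rose late gave other values in these comparisons. The yolk gene vit-6 had 668 CPM in course A and 26.6 CPM in course B at the shared times (-4.87 ± 0.87, lower in 7 of 8 pairs), and -1.03 ± 0.49 (adjusted p = 0.109) against course A 3 h earlier. cyb-2.2 had -1.78 ± 0.13 at the shared times and -0.92 ± 0.22, short of the minimum, against course A 3 h earlier. Of 49 sperm genes 9 were lower in course B at the shared times (6 adjusted over the list alone), whereas 16 of 46 were higher against course A 3 h earlier (16). These counts were 22 and 10 with total counts as the only scaling. Of 41 germline and oocyte genes 5 were lower at the shared times (5), such as spo-11 at -1.26 ± 0.11, and 8 were higher against course A 3 h earlier (8). Under that scaling 10 were lower at the shared times, and 2 were higher and 1 lower against course A 3 h earlier. The 3 h exceed the median offset of 2.73 h, so genes that rise steeply can come out higher in course B for that reason alone. Whether this gave the higher counts of the sperm, germline and collagen lists was not tested. Of 143 cuticle collagens 9 were higher and 2 lower at the shared times (6 and 1; 7 and 4 with total counts as the only scaling), and 71 of 144 were higher and 2 lower against course A 3 h earlier (71 and 2), where their median was 1.04, or 0.76 with total counts as the only scaling (52 higher, 3 lower). The camera test of this list had an adjusted p of 8.21e-12, and an adjusted p of 0.432 with an estimated correlation. col-36 had a mean of 0.00659 CPM at the shared times in course A, from 1 count, and 2.63 CPM in course B.

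Among the other lists, 6 of 12 lysozymes were lower in course B both at the shared times and against course A 3 h earlier (6 and 6 adjusted over the list alone), and of the C-type lectins 11 were higher and 22 lower at the shared times (11 and 24). Of 169 detoxification genes 12 were higher and 18 lower (12 and 18), and of 15 propionate and vitamin B12 genes 2 were higher and 3 lower (2 and 3). Scaling by total counts alone gave 9 lectins higher and 37 lower, 8 detoxification genes higher and 24 lower, and 2 propionate and vitamin B12 genes higher and 5 lower. The mitochondrial chaperone gene hsp-60 was 1.26 ± 0.18 higher, with 3 of 14 heat shock genes called (3; 1 with total counts as the only scaling), the muscle troponin gene mup-2 1.2 ± 0.15 higher, the Argonaute gene alg-2 1.15 ± 0.11 higher and the neuronal gene ida-1 1.05 ± 0.07 higher, each in 8 of 8 pairs. With total counts as the only scaling, mup-2 (0.95), alg-2 (0.90) and ida-1 (0.80) came below the minimum. The camera test called 11 lists at the shared times. They were body wall muscle (adjusted p = 1.16e-07), ribosomal proteins (3.64e-06), heat shock (4.06e-05), heterochronic (0.000353), neurons (0.000353), regulators (0.00206), core histones (0.00209) and collagens (0.00874) as higher in course B, and sperm (0.000196), lysozymes (0.000353) and yolk (0.0344) as lower. With an estimated correlation the adjusted p values were, in the same order, 0.201, 0.600, 0.101, 0.0516, 0.243, 0.101, 0.504 and 0.504, and 0.504, 0.0516 and 0.421, so that 0 lists passed (5 at an unadjusted p under 0.05). The medians of the lists called higher depend on the scaling and, by total counts alone, went from 0.43 to 0.18 (muscle), 0.24 to -0.01 (ribosomal proteins), 0.65 to 0.40 (heat shock), 0.42 to 0.17 (heterochronic), 0.21 to -0.04 (neurons), 0.69 to 0.44 (regulators), 0.36 to 0.11 (core histones) and 0.31 to 0.06 (collagens). Under it 0 heterochronic genes were called in place of 2, and of the core histones 0 were higher and 3 lower in place of 1 and 1.

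Over all genes, 1491 of 15639 differed at the shared times, 280 higher and 1211 lower in course B, and 2014 of 15591 differed against course A 3 h earlier, 758 higher and 1256 lower. The count of 1491 was 936 with no block, 2349 with a curve in time over all libraries and 4552 with no minimum. The median difference of all tested genes was -0.13 at the shared times and -0.05 against course A 3 h earlier, and -0.38 and -0.34 with total counts as the only scaling. The split was 146 higher and 2235 lower at the shared times, and 381 higher and 2326 lower against course A 3 h earlier, under that scaling. With course B rescaled so that the median difference at the shared times was 0, it was 427 higher and 891 lower there.

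**Figure D4:**
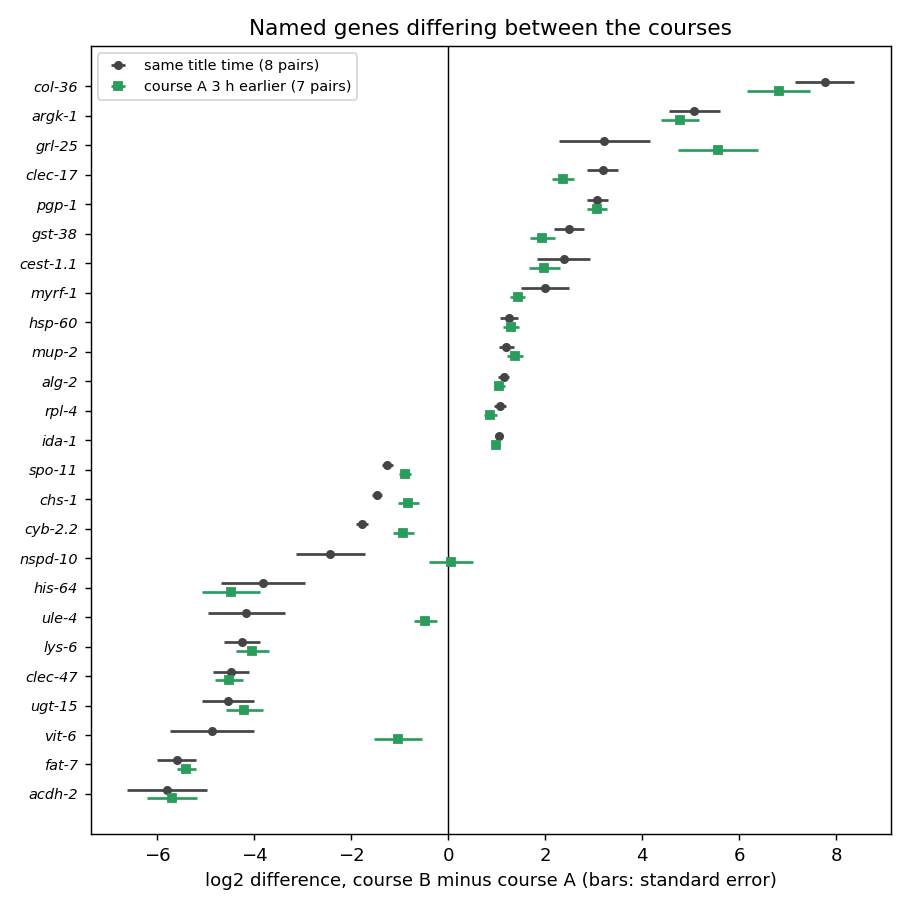
Difference between the courses for the named genes, course B minus course A on the log2 scale (x axis; bars are standard errors of the fit), at the same title time (8 pairs, circles) and against course A 3 h earlier (7 pairs, squares), with genes on the y axis. The squares of argk-1 and acdh-2 lie near their circles (4.78 and 5.08; -5.69 and -5.79), and that of vit-6 moves from -4.87 to -1.03.

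The last question was whether the cycle or the trend of a gene differed between the courses. The cycle of the intestinal gene pgp-1 spanned 0.45 in course A and 1.07 in course B, and its trend was -1.21 and 0.23 (difference in trend 1.49, adjusted p = 0.00455). Among genes chosen after their values were seen, the lysozyme gene lys-7 rose from a mean of 49.5 to 93.9 CPM in course A and went from 76.7 to 53.4 CPM in course B (difference in trend -2.19, adjusted p = 0.000146). The cytochrome P450 gene cyp-35A3 went from 28.6 to 59.0 CPM and from 4.49 to 2.91 CPM (-2.51, adjusted p = 0.000819), and col-19, a collagen gene of the adult cuticle, from 0.0397 to 399 CPM and from 0.123 to 44.8 CPM. At title times the cycle differed for 5960 of 16076 genes, and with course B moved back by the median offset for 11. The trend differed for 74 genes, 25 of them higher in course B, and for 2126 at an unadjusted p under 0.05. The count of 74 was 33 with a 7 h period, 27 with 9 h, 417 with quadratic time, 217 with DESeq2 and 304 with limma. Other exchanges of libraries between the courses gave as many genes, so chance cannot be excluded for these 74.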

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

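In this part, the test with course B moved back by its offset was chosen, and the bound on the offset with harvest times was set, after the result was seen. The use of harvest times was fixed beforehand. At title times the cycle of 5960 of 16076 genes differed between the courses by the interaction test, which included 40 of the 45 named oscillation genes, such as mlt-10 and grh-1. Exchanging libraries of the same time between the courses gave at most 4480 genes in the other draws, and the real split was the 1 of 100 with as many. The exchanged libraries were of unlike stages, as course B lay behind course A, and libraries at times without a partner kept their course. These draws are therefore no clean measure of chance. As cultures were not replicated, chance differences between cultures were not addressed.

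The later peaks of course B, by 2.73 h in the median, were weighed against the times themselves. A shift of the course A titles by 1 h as the whole cause needs an offset near 0 with harvest times, and the offset was 1.73 h, which argues against that shift alone. A delay of course B that stayed the same predicts a lag that spans less than 1 h, and the course B libraries from 24 to 36 h lay 2.25 to 3 h behind course A, a span of 0.75 h, which is consistent with such a delay. The period with the most calls was 8.75 h in course A (9.25 h with limma) and 7.75 h in course B, however, and since unequal periods would let the lag change with time, a delay that stayed the same is not shown. Which difference between the cultures set the delay stays open, since bacterium, medium and day were never varied apart, and no biological explanation was tested.

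With course B moved back by the median offset, the cycle of 11 genes still differed. They were C05C10.3, C09B8.4, C23H5.8, C35A5.3, cest-33, folt-2, dhgd-1, pgp-1, ugt-53, Y39B6A.1 and Y8A9A.2, and 4 of the 11 had been called oscillating in both courses. The folate transporter gene folt-2 spanned 2.33 in course A and 0.66 in course B (adjusted p = 0.00325), and for pgp-1 the adjusted p was 0.0419.

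The trend of 74 genes differed between the courses by the interaction test (33 with a 7 h period, 27 with 9 h, 417 with quadratic time, 217 with DESeq2 and 304 with limma). Among the genes named for the course difference, the trend in course B minus that in course A was 1.82 for clec-17, 1.49 for pgp-1, 1.68 for gst-38 and -1.72 for clec-47 (log2 over 15 h). Among others, chosen after their values were seen, the trend of the steroid receptor gene daf-12 differed by -1.15, that of the lectin gene clec-67 by 1.74 and that of the histone gene his-1, whose copies can share reads, by 2.84. As many genes or more came from 6 of 100 exchanges of libraries, the real one included, so chance cannot be excluded. The highest other count was 1604, when the libraries of 30, 32, 34 and 36 h were exchanged, which is several times the real count. The other 4 exchanged the library of 36 h, in 2 of them also that of 34 h, together with that of 22 or 24 h, and gave 841, 533, 201 and 196 genes. Course B lay 2.25 to 3 h behind course A from 24 to 36 h, so such exchanges join libraries of unlike stages and can make trends differ. They are therefore no clean measure of chance, and leave open whether the 74 genes arose by it. The courses also ended at unlike stages, as course B at 36 h was most like course A at 33.75 h.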

How the results depend on the processing

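The alternatives with total counts as the only scaling, the median difference set to 0, course A 3 h earlier, course B moved back, peaks around the median offset and limma for the best period were chosen after the data were seen. Counts of oscillating, trend and differing genes stayed within 1.5 times their value with DESeq2's size factors and without the low count filter. The exceptions follow, and the cause was not tested where none is given. With a 7 h period 2054 genes oscillated in course A, 36 in course B, 21 in both and 2 in both with peaks within 2 h, and with 9 h the last 3 counts were 0, 0 and 0 with edgeR (2514 genes in course B and 2088 in both at an unadjusted p under 0.05; 1696 in course B with DESeq2, 0 with limma). A 4-fold minimum, stricter by construction, left 2112, 1905, 1563 and 30, and the 8 shared times alone, fewer libraries, left 1441 in course A, 1170 in both and 27. The count of 88 with peaks within 2 h was 38 with limma, 158 with no minimum, 24 within 1 h, 2127 with harvest times, 2445 around the median offset and 2457 with no limit. Left-out libraries gave 38 to 131 for it, 3277 to 3683 oscillating genes in course A, 2370 to 3015 in course B, 2598 to 3459 trend genes in both courses and 1054 to 1653 genes at the shared times. With no minimum 6896 trend genes were called in course B. The offset was 1.73 h with harvest times, and limma's best period in course A was 9.25 h. At the shared times 936 genes differed with no block, 2349 with a curve in time, 4552 with no minimum and 2381 with total counts, and 2707 with total counts against course A 3 h earlier. The trend differed between the courses for 33 genes with 7 h, 27 with 9 h, 417 with quadratic time, 217 with DESeq2 and 304 with limma, and the cycle for 11 with course B moved back. With an estimated correlation, camera called 2 lists for the trend in course A and 1 in course B, and 0 for the difference between the courses at the shared times (5 at an unadjusted p under 0.05) and 0 against course A 3 h earlier (2 at an unadjusted p under 0.05).

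The difference of nspd-10, a sperm gene with near-identical relatives, reversed from -2.42 to 0.065 against course A 3 h earlier and to 0.11 with DESeq2's size factors there. Its adjusted p, 0.0388, rose to between 0.0581 and 0.0941 without the library of 26, 28, 30 or 32 h of either course. No other named gene changed direction under the alternatives run. Over all of these, the named oscillation values kept their side of the threshold 261 times, lost it 90 times, of which 38 with 7 h and 38 with 9 h, and gained it 9 times. Named trends kept it 325 times and lost it 19 times, and named differences kept it 274 times and lost it 41 times. Leaving out 1 library ended the call of 11 of 38 named oscillating genes, 14 of 43 trend genes and 4 of 27 differences. Depth limits what can be said of genes near 0.0932 to 0.186 CPM, the level that 3 counts make in a library.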

Other observations

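The gene families in this part, the split of the lower genes by their trend and its repeat in other libraries, the scalings by total counts and to a median difference of 0, and the comparison of collagens with the hedgehog-related and molting lists were tests chosen after the result was seen. Taken by the letters of their names, 100 families that no fixed list holds were tested (473 Fisher's exact tests, adjusted together). Several with roles in neurons fell through both courses as a share of whole-worm RNA. Of 43 ligand-gated channel genes (lgc) 18 fell (adjusted p = 1.20e-07), of 42 potassium channel genes (twk) 17 (5.23e-07), of 28 guanylate cyclase genes (gcy) 13 (3.84e-06), of 21 acetylcholine receptor genes (acr) 9 (0.000439) and of 43 neuropeptide receptor genes (npr) 13 (0.000463), against 7.84% of all genes. With total counts as the only scaling 18, 18, 15, 10 and 14 fell, while the count over all genes went from 1170 to 1327. The neprilysin-like peptidase genes (nep) rose, 13 of 22 (9.67e-05), as did the irld genes, 9 of 14 (0.000829), and 13 and 9 rose under that scaling as well.

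Other families cycled or were lower in course B. All 16 of 16 tested idpp genes oscillated in both courses (adjusted p = 1.33e-10), as did 10 of 12 fipr genes (4.08e-05), with peaks around 27.9 h in course A and 30.6 h in course B, 18 of 35 acyltransferase-like genes (oac; 8.48e-05), 14 of 26 cuticlin-like genes (cutl; 0.000439) and 15 of 31 carboxylesterase genes (cest; 0.000829). Against course A 3 h earlier, 13 of 19 tested chemoreceptor genes of the str family were lower in course B (2.30e-08), 9 of 16 of the srh family (4.96e-05) and 8 of 18 of the sre family (0.000829), next to 33 of 125 F-box genes of the fbxa family (1.01e-07), with 8.06% of all genes lower. With total counts as the only scaling 13, 10, 12 and 50 were lower, but the count over all genes also went up, from 1256 to 2326 of 15591. Members of these families resemble each other and can share reads.

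Most genes that differed at the shared title times were lower in course B, 1211 of 1491 (81.2%), a share that depends on the scaling, with 93.9% by total counts alone, and 56.9% (DESeq2's size factors) to 85.9% (total counts) against course A 3 h earlier. Course B rescaled to a median difference of 0 over all tested genes gave 67.6% (95% binomial interval over genes 65.0 to 70.1). Most called genes were still lower, which argues against an offset of that size as the whole cause. DESeq2's size factors, with 79.8%, moved the median only from -0.13 to -0.10 and decide nothing. All intervals in this paragraph treat genes as independent, although they share the same libraries, so the intervals are likely too narrow. If course A had only been further in development at the same title time, fewer genes were predicted to differ from course A 3 h earlier, but 2014 did. That count cannot decide it, since it also depends on the spread around the fit, which differed between these comparisons. The median went from -1.52 to -0.147 (95% bootstrap interval -0.223 to -0.0967) for the 532 lower genes that rose over time in both courses. It went from -1.68 to -1.49 (-1.54 to -1.42) for the 679 others, 599 of them tested. As these medians reuse course B libraries that chose the genes, genes were also chosen as lower at 4 of the 8 shared times (0 at an adjusted p under 0.05, so at an unadjusted p). They were measured in other libraries, in 2 such arrangements. Only the choice as lower was kept apart in this way, since the split into rising genes and others used all libraries of both courses. Rising genes gave -0.0712 and -0.467 (-0.672 to -0.381), where all rising genes had 0.281 and 0.363. They thus came near 0, as course A being further on predicts, but stayed below the median of all rising genes, so this fits only in part. The others gave -1.26 (-1.31 to -1.22) and -1.45 (-1.56 to -1.36), against -0.0638 and -0.0877 for all genes that did not rise. This argues against course A being further on as the cause for those lower genes. Which scaling is right for these cultures stays open, as do bacterium, medium and day for these others, which cannot be separated in this design. At each shared time more genes had counts in course A than in course B, despite fewer total counts (16505 and 16161 genes at 24 h). A difference between the libraries that does not come from the cultures was not tested and stays open as well.

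Cuticle collagens were higher in course B than in course A 3 h earlier, with a median of 1.04 over 144 genes (95% bootstrap interval over genes 0.914 to 1.22; camera adjusted p = 8.21e-12), but the list did not pass with an estimated correlation (adjusted p = 0.432). Other genes of matched length had a median of -0.229 (1112 genes), and other oscillating genes with like peak time and amplitude -0.0380 (341 genes), which argues against a length bias and against a remaining misfit of the cycle. These genes were not matched on trend, however, while 42 of 130 collagens rose in both courses. The lag of course B was 2.25 h at 24 and 36 h, short of the 3 h used. A remaining misfit of stage was therefore not tested. A larger share of skin RNA in course B as the whole cause is argued against by the hedgehog-related genes, at 0.110 (-0.0801 to 0.349), and the molting enzymes and matrix genes, at 0.352 (0.118 to 0.491), or -0.17 and 0.07 by total counts alone. These intervals treat genes as independent and are likely too narrow. As 9 hedgehog-related genes were higher and 1 lower, and 4 molting genes higher and 0 lower (camera adjusted p = 0.0152, adjusted p = 0.498 with an estimated correlation), a larger share as a part of the cause stays open, and reads shared between collagens were not tested. A higher collagen output that goes with the culture of course B stays a hypothesis, with bacterium, medium and day untested.

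Whether chance could give the other counts was tested by shuffling the times of a course or by exchanging libraries of the same time between the courses. The real arrangement was the 1 of 100 with as many genes in each of these tests, the least these draws can give. A random order of the times thus does not readily give such counts. The exchanges joined libraries of unlike stages, so they are no clean measure of chance for the difference at the shared times. Shuffling also breaks the likeness of neighbouring times, so it does not show an 8 h period as such. As cultures were not replicated, chance differences between cultures were not addressed. For oscillating genes the real and the highest other count were 3619 and 1230 in course A, 3147 and 2521 in course B and 2457 and 0 in both courses. For trend genes they were 5375 and 3503 in course A, 4224 and 624 in course B and 3407 and 0 in both courses, and for genes differing at the shared times 1491 and 351.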
